A study of Homo sapiens with 20 samples.

How the data were processed

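RNA was measured in 20 samples of hTCEpi, a line of human corneal epithelial cells immortalized with telomerase. The cells were given recombinant human SPARC at 0, 0.05, 0.5 or 5 µg/ml for 24 hours, with 5 replicates at each dose. The control is the 0 µg/ml group. The labels do not say whether the 5 replicates of a group came from separate cultures. Per the labels, ribosomal RNA was depleted enzymatically, cDNA was primed with random hexamers, and paired reads were taken on a NovaSeq.

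The deposited table of counts holds whole read counts per Ensembl gene, which the authors made from the reads. The authors' notes name bcl2fastq, STAR 2.7.9a, Subread featureCounts 2.0.3, Salmon 1.5.2, edgeR and limma, and genome build GRCh38. The release of the gene annotation and the strand setting of the counting are not given in the sources used here, so counts of antisense genes may hold reads of the gene on the other strand, and counts of pseudogenes may hold reads of their parent genes. The authors also deposited 3 comparison tables, 1 for each dose against control. Per the file headers these tables hold log2 fold changes with intervals, a p-value and an adjusted p-value for each gene. The authors' log2 values per sample in the same tables were equal to log2 counts-per-million plus a constant per sample, between −0.027 and 0.032.

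The table of counts had 60871 entries for 60671 gene identifiers. For 168 identifiers that stood on 368 entries with equal counts, 1 entry was kept, which removed between 0.278% and 0.296% of the counts of a sample. Counts per sample then summed to between 31955358 and 50112286. Genes with enough counts to test were kept with filterByExpr of edgeR (minimum count 10), which left 22938 genes. Values are counts-per-million (CPM) scaled with trimmed mean of M values (TMM) factors, given as mean ± SD over the 5 samples of a group, and log2 CPM used a prior count of 2. In the 40 pairs of replicates of equal dose, the chi-square per gene at genes with a summed count of at least 200 was between 3.65 and 7.07, where counting noise alone gives about 1. The common biological coefficient of variation was 6.68%. PCR copies cannot be told from separate molecules, so limits computed from counts cover counting error only.

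Genes were compared with the quasi-likelihood F-test of edgeR 4.0.16 with robust estimates, in R 4.3.3, with all 4 groups in 1 model of group means. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was said to rise or fall when its adjusted p was under 0.05. The comparisons were each dose against control, each pair of doses, any difference among the 3 doses and control, and a trend per dose step. Log2 fold changes are given with their standard error (SE).

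The genes named were chosen by a rule written before the data were examined. For each dose against control the rule takes the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, a gene symbol, a mean of at least 1 CPM in either group and all 5 treated samples on the same side of the control mean. It adds up to 3 members of each gene list with the smallest p, and SPARC itself. The trend and the differences between doses take 5 rises and 5 falls. Members of the gene lists may be named as examples, and any other gene is said to have been chosen after its values were seen.

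Before the data were examined, 36 gene lists were written for this cell type and treatment, and 35 were tested. They cover limbal and basal epithelial cells, stratified epithelial differentiation, ocular surface mucins, cell junctions, extracellular matrix and matricellular proteins, basement membrane and hemidesmosome, integrins and focal adhesion, epithelial-mesenchymal transition, TGF-beta response, matrix proteases and inhibitors, inflammatory and NF-kB targets, interferon response, EGFR ligands and immediate early genes, YAP/TAZ targets, the Notch pathway and Wnt targets. They also cover G1/S replication, G2/M mitosis, replication-dependent histones, p53 targets, the unfolded protein and ATF4 response, NRF2 oxidative stress, metallothioneins and metal response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, actin cytoskeleton and SRF targets, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins and the circadian clock. The rest are markers of corneal stroma and fibroblasts, conjunctival and goblet cells, immune cells, and endothelial cells and melanocytes, and SPARC receptors and partners. Ocular surface mucins were not tested, because only MUC20 and MUC1 had enough counts. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 35 lists. For 5 lists chosen after seeing the data, mean log2 CPM was compared between groups with 2-sided exact permutation tests over the 252 arrangements of 10 samples, adjusted over 30 tests.

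Gene positions, lengths and GC content came from a GENCODE release 29 annotation of GRCh38, which held 22492 of the 22938 genes tested (98.1%). Of 17932 genes with a symbol in both sources, 17305 had the same symbol.

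The alternatives fixed before the data were examined were RLE size factors, library sizes with no TMM factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a stricter filter (above 1 CPM in at least 5 samples), protein-coding genes alone, only the groups compared, replicate number as a block, leaving out each sample in turn, and, for lists, camera with an estimated correlation and fry. A correction for GC content and transcript length, thinning every library to the smallest, leaving out 2 SPARC 5 libraries, and library sizes only for lists and named genes were chosen after seeing the data. The test was also run on counts simulated from the control means, in which genes were raised or lowered in the SPARC 5 group. It called 35% of 60 genes changed 1.2-fold, 59.7% of 72 changed 1.5-fold and 57.4% of 68 changed 2-fold, and 7.2% of its 111 calls were false. Some genes that the rule took are not reported here, and their values were left out of the search for single values far from the rest of their group. Reads and the Salmon output were not analysed here.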

Results

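RNA of hTCEpi cells was sequenced after 24 hours without SPARC (control) or with recombinant human SPARC, a secreted matricellular glycoprotein that binds collagen. Doses were 0.05, 0.5 and 5 µg/ml, called SPARC 0.05, SPARC 0.5 and SPARC 5, with 5 samples in each of the 4 groups. Total counts per sample were 34.9 ± 3.09 M in control (mean ± SD, n = 5), 37.3 ± 3.52 M at SPARC 0.05, 40.9 ± 6.63 M at SPARC 0.5 and 37.5 ± 3.56 M at SPARC 5, with a range over all 20 samples of 31955358 to 50112286. Transcripts of the mitochondrial genome took 3.60 ± 0.081% of counts in control, 3.78 ± 0.153% at SPARC 0.05, 3.69 ± 0.017% at SPARC 0.5 and 3.47 ± 0.296% at SPARC 5. The SPARC gene itself had between 0 and 23 counts per sample and was not tested. In a sample with no counts of it, 3 counts would be 0.0722 CPM at SPARC 0.05 replicate 5 and 0.0599 CPM at SPARC 0.5 replicate 3, so its own expression was near the limit of this depth.

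The first principal component of log2 CPM carried 8.3% of the variance and put the controls between −29.24 and −10.41 and the SPARC 5 samples between 16.75 and 34.31. The second component carried 6.6% and set SPARC 5 replicate 2 (48.23) and replicate 5 (−40.11) apart from the other samples. Libraries also differed in how log2 CPM followed the GC content of genes. Each gene's mean log2 CPM over the 20 libraries was first subtracted, so the correlations with GC content are relative to the other libraries. They were taken across genes with a mean of at least 1 CPM, which are not independent replicates. The correlation was 0.128 ± 0.106 in control, −0.036 ± 0.032 at SPARC 0.05, −0.060 ± 0.044 at SPARC 0.5 and −0.040 ± 0.084 at SPARC 5 (mean ± SD of 5 libraries).

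**Figure D1:**
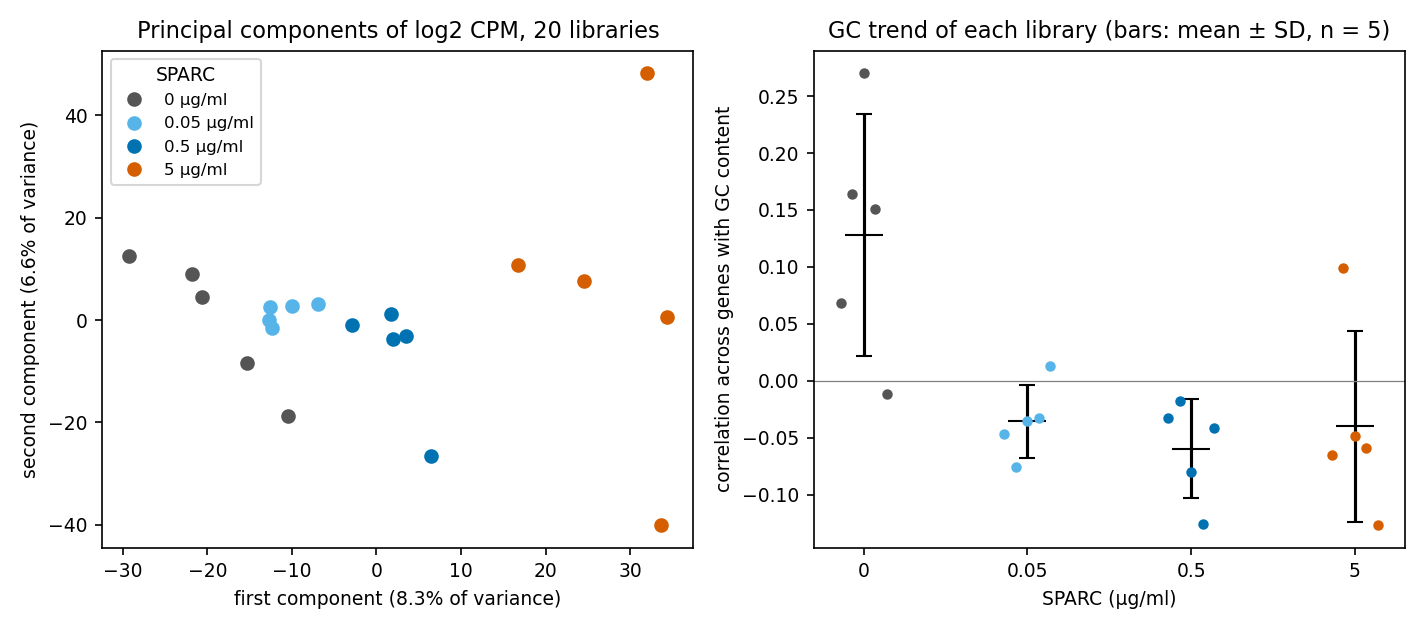
Left, the 20 libraries on the first and second principal components of log2 CPM, colored by SPARC dose. Right, the correlation across genes of GC content with each library's log2 CPM minus the mean of the 20 libraries, with mean ± SD (n = 5) per dose. The controls average 0.128 and SPARC 0.05 averages −0.036.

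The comparison of SPARC 5 with control asks which transcripts of corneal epithelial cells differ after a day at the highest dose. Several genes of the extracellular matrix and of cell attachment to it were among those that rose. FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436172 of GRCh38), which encodes fibronectin, went from 688 ± 48.3 CPM in control to 2540 ± 92.3 CPM (mean ± SD, n = 5 each), a log2 fold change of 1.88 ± 0.06 (SE; adjusted p = 9.53e-14). THBS1, the matricellular protein thrombospondin, went from 3420 ± 334 to 9000 ± 440 CPM (1.40 ± 0.06, adjusted p = 2.98e-12). TGFBI (ENSG00000120708, chromosome 5, 136028895 to 136063818), a TGF-beta-induced matrix protein abundant in the cornea, went from 464 ± 8.17 to 971 ± 32.3 CPM (1.06 ± 0.02, adjusted p = 9.29e-62). ITGB6 (ENSG00000115221, chromosome 2, 160099666 to 160200313), an epithelial integrin subunit that binds fibronectin and latent TGF-beta, went from 53.8 ± 1.61 to 137 ± 7.14 CPM (1.35 ± 0.04, adjusted p = 2.44e-52).

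Among the other large rises at SPARC 5 were XYLT1, the enzyme that starts glycosaminoglycan chains on proteoglycans (log2 3.04 ± 0.23, from 0.657 ± 0.148 to 5.42 ± 0.411 CPM), and the metalloprotease gene ADAM19 (2.42 ± 0.46). IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874), which binds insulin-like growth factors, had the largest rise named, from 0.172 ± 0.153 to 4.48 ± 1.1 CPM (4.69 ± 0.57, adjusted p = 9.47e-06). The sulfotransferase gene SULT1B1 rose by 1.92 ± 0.19, and NLRP3, an inflammasome sensor, by 1.77 ± 0.34 to 1.76 ± 0.607 CPM. The largest falls named here were in genes of low counts, apart from KRT15. FLG, the barrier protein filaggrin, fell by 1.71 on the log2 scale, from 1.05 ± 0.267 to 0.323 ± 0.119 CPM, and ANKRD22 fell by 1.28, from 6.38 ± 1.28 to 2.63 ± 0.483 CPM. KRT15 (ENSG00000171346, chromosome 17, 41513743 to 41522529), a keratin of basal and limbal cells, was the most abundant of them and went from 114 ± 24.5 to 53.1 ± 7.52 CPM (−1.11 ± 0.14, adjusted p = 2.98e-05). SMOC1, a member of the SPARC family, changed by −1.08 ± 0.22.

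The edgeR quasi-likelihood test called 2665 of 22938 genes at SPARC 5, of which 1615 rose and 1050 fell. The balance of directions depended on the scaling: with library sizes only, 3190 genes were called, of which 999 rose and 2191 fell, so that the share of rises went from 60.6% to 31.3%. The median log2 fold change of all genes was −0.007 with TMM and −0.054 with library sizes only. Every gene named in the preceding paragraphs on SPARC 5 kept its direction and its call under both scalings. The largest rises and falls were named only if all 5 treated samples lay on the same side of the control mean, so this is a condition of the choice and not a finding. The named members of gene lists were chosen without that condition, and each gene called also had all 5 on that side. Genes that rose at SPARC 5 had a median transcript length of 4663 bases and GC content of 45.4%, against 3385.5 bases and 55.7% for genes that fell. After a correction of each library for GC content and length, chosen after seeing the data, 1969 of the 2665 were called in the same direction. The median size of the log2 fold change of the 2665 went from 0.21 to 0.197.

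Matrix lists were called higher at SPARC 5. Of 24 extracellular matrix and matricellular genes tested, 14 rose, 2 fell and 8 did not pass (18 passed adjusted over the list alone; camera adjusted p = 8.2e-15), with COL12A1 up 0.58 ± 0.03. Of 22 basement membrane and hemidesmosome genes, 14 rose, 3 fell and 5 did not pass (19 adjusted over the list alone; camera adjusted p = 5.08e-11). These included COL7A1, the collagen of anchoring fibrils (0.58 ± 0.03, from 434 ± 19.9 to 649 ± 29.5 CPM), COL4A1 (0.63 ± 0.03) and the laminin chain LAMB3 (0.67 ± 0.07), while HSPG2, the proteoglycan perlecan, changed by −0.26 ± 0.06. Of 21 integrin and focal adhesion genes, 15 rose, 1 fell and 5 did not pass (17 adjusted over the list alone; camera adjusted p = 9e-14), among them ITGA2 (0.37 ± 0.03). Of 25 TGF-beta response genes, 13 rose, 0 fell and 12 did not pass (15 adjusted over the list alone; camera adjusted p = 4.39e-13). PMEPA1, a TGF-beta-induced inhibitor of the pathway, rose from 37.6 ± 2.42 to 126 ± 6.05 CPM (1.74 ± 0.05), SMAD7 rose by 0.37 ± 0.08 and TGFB1 itself by 0.21 ± 0.03. Of 18 genes of epithelial-mesenchymal transition, 8 rose, 0 fell and 10 did not pass (12 adjusted over the list alone; camera adjusted p = 6.74e-12), with the transcription factor SNAI2 up 0.41 ± 0.05. Of 20 matrix proteases and inhibitors, 8 rose, 1 fell and 11 did not pass (11 adjusted over the list alone; camera adjusted p = 7.07e-06). The membrane protease MMP14 rose by 0.28 ± 0.03, and the plasminogen activator PLAT changed by −0.36 ± 0.08. Several genes stand in more than 1 of these lists.

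Cytoskeletal and growth-control lists were called higher at SPARC 5 as well. Of 21 actin cytoskeleton and SRF target genes, 17 rose, 0 fell and 4 did not pass (19 adjusted over the list alone; camera adjusted p = 7.84e-17), including ACTB (0.23 ± 0.02, from 5110 ± 92.2 to 6000 ± 129 CPM) and TPM4 (0.28 ± 0.03). Of 23 YAP/TAZ targets, 16 rose, 1 fell and 6 did not pass (20 adjusted over the list alone; camera adjusted p = 3.86e-11), including CCN1 (0.61 ± 0.05) and CCN2 (0.39 ± 0.07). Of 29 cholesterol and fatty acid synthesis genes, 16 rose, 1 fell and 12 did not pass (21 adjusted over the list alone; camera adjusted p = 3.43e-07), including MSMO1 (0.28 ± 0.03), while SREBF1 changed by −0.12 ± 0.03. Of 24 genes of the unfolded protein and ATF4 response, 8 rose, 2 fell and 14 did not pass (11 adjusted over the list alone; camera adjusted p = 0.000129), including the chaperones CALR (0.29 ± 0.02) and HSPA5 (0.28 ± 0.02). Of 17 limbal and basal epithelial genes, 7 rose, 2 fell and 8 did not pass (11 adjusted over the list alone; camera adjusted p = 0.000238). COL17A1 (0.35 ± 0.03), ITGB4 (0.27 ± 0.02) and KRT14 (0.49 ± 0.07) were among the rises, and KRT15 and the neurotrophin receptor NGFR (−0.52 ± 0.09) were the falls. Of 11 metallothionein and metal response genes, 3 rose, 0 fell and 8 did not pass (5 adjusted over the list alone; camera adjusted p = 0.00161), including the zinc transporter SLC39A10 (0.30 ± 0.05).

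Camera called the NRF2 oxidative stress list and the inflammatory and NF-kB list lower at SPARC 5. Of 19 NRF2 genes, 0 rose, 7 fell and 12 did not pass (7 adjusted over the list alone; camera adjusted p = 2.96e-05). The ferritin light chain FTL went from 223 ± 13.2 to 173 ± 6.82 CPM (−0.36 ± 0.03, adjusted p = 1.71e-17). Of 31 inflammatory and NF-kB targets, 1 rose, 6 fell and 24 did not pass (14 adjusted over the list alone; camera adjusted p = 0.00305). The complement gene C3 (−0.50 ± 0.06) and the acute-phase gene SAA1 (−0.60 ± 0.08) were among the falls, and PTGS2, an enzyme of prostaglandin synthesis, was the rise (0.73 ± 0.15). This list's call was lost with an estimated correlation (adjusted p = 0.324 with an estimated correlation), and its mean log2 CPM did not pass (−0.133, 95% permutation interval −0.320 to 0.071, exact permutation p = 0.135), so a fall of the list as a whole is not established. Of 16 Wnt targets, 3 rose, 0 fell and 13 did not pass (3 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.111 with an estimated correlation). SFRP1, a secreted Wnt antagonist, was among the rises (0.27 ± 0.03). Of 24 cell junction genes, 5 rose, 2 fell and 17 did not pass (7 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.118 with an estimated correlation). The desmosomal gene DSP rose by 0.19 ± 0.02, and CLDN1, a tight junction claudin, changed by −0.52 ± 0.06. With library sizes only, neither the Wnt list (camera adjusted p = 0.0548) nor the cell junction list (0.303) passed, and the cell junction list did not pass after a correction for GC content and length (0.183). The other 13 of the 16 lists called at SPARC 5 kept their calls with an estimated correlation.

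The remaining 19 lists did not pass camera at SPARC 5. Among epithelial states, stratified differentiation (adjusted p = 0.604) had 3 genes that rose, such as KRT6A (0.41 ± 0.05), and 3 that fell, such as PPL (−0.30 ± 0.04), of 26 (8 adjusted over the list alone). Conjunctival and goblet markers (adjusted p = 0.472) had 1 rise and 1 fall of 9 (4 adjusted over the list alone). The rise was KRT7, a keratin of simple epithelia, from 622 ± 39.1 to 1100 ± 18.4 CPM (0.82 ± 0.03), and the fall was KRT18 (−0.17 ± 0.03). Corneal stroma and fibroblast markers (adjusted p = 0.625) had 1 rise, PDPN (0.18 ± 0.04), and 1 fall, ALDH3A1 (−0.85 ± 0.12), an aldehyde dehydrogenase that corneal epithelium also expresses, of 6 (2 adjusted over the list alone). Endothelial and melanocyte markers (adjusted p = 0.188) had 0 rises and 1 fall of 7 (2 adjusted over the list alone), and immune cell markers (adjusted p = 0.154) had no call among 4 genes (0 adjusted over the list alone).

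Among signalling lists at SPARC 5, EGFR ligands and immediate early genes (adjusted p = 0.178) had 5 rises, such as JUN (0.32 ± 0.04) and KLF6 (0.40 ± 0.03), and 2 falls of 32 (10 adjusted over the list alone). The Notch pathway (adjusted p = 0.268) had 3 rises, such as JAG1 (0.22 ± 0.03), and 2 falls of 14 (8 adjusted over the list alone), and the p53 targets (adjusted p = 0.318) had 4 rises, such as CDKN1A (0.56 ± 0.08), and 1 fall of 22 (5 adjusted over the list alone). SPARC receptors and partners (adjusted p = 0.336) had 4 rises, such as ITGB5 (0.33 ± 0.03), and 3 falls of 13 (7 adjusted over the list alone). The interferon response (adjusted p = 0.188) had 0 rises and 4 falls of 24 (5 adjusted over the list alone), and the circadian clock (adjusted p = 0.528) had 1 rise, BHLHE40 (0.53 ± 0.04), and 1 fall of 18 (2 adjusted over the list alone). Hypoxia and glycolysis (adjusted p = 0.528) had 5 rises, such as NDRG1 (0.76 ± 0.05), and 2 falls, CA9 (−0.71 ± 0.17) and VEGFA (−0.30 ± 0.05), of 21 (8 adjusted over the list alone). Its median log2 fold change was −0.002 and the direction of its test was up. The circadian list also had a test direction of up, with a median of 0.028 and a mean of −0.031.

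Lists of growth and housekeeping had few calls at SPARC 5. G2/M mitosis (adjusted p = 0.528) had 0 rises and 1 fall of 30 (0 adjusted over the list alone), G1/S replication (adjusted p = 0.789) had no call among 27 (0 adjusted over the list alone), and replication-dependent histones (adjusted p = 0.663, and 0.00784 as higher after the correction for GC content and length) had 1 rise of 18 (1 adjusted over the list alone). Cytosolic ribosomal proteins (adjusted p = 0.677) had 1 fall of 28 (1 adjusted over the list alone), and mitochondrially encoded genes (adjusted p = 0.411) had no call among 13 (0 adjusted over the list alone). Nuclear oxidative phosphorylation (adjusted p = 0.0847) had 1 rise and 3 falls, such as CYC1 (−0.14 ± 0.03), of 26 (5 adjusted over the list alone), and heat shock (adjusted p = 0.154) had 1 fall, HSPD1 (−0.11 ± 0.02), of 14 (2 adjusted over the list alone). The heat shock list had a median of −0.044 and a mean of 0.006. With library sizes only, both lists passed as lower, with adjusted p = 0.00228 for nuclear oxidative phosphorylation and 0.00825 for heat shock.

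**Figure D2:**
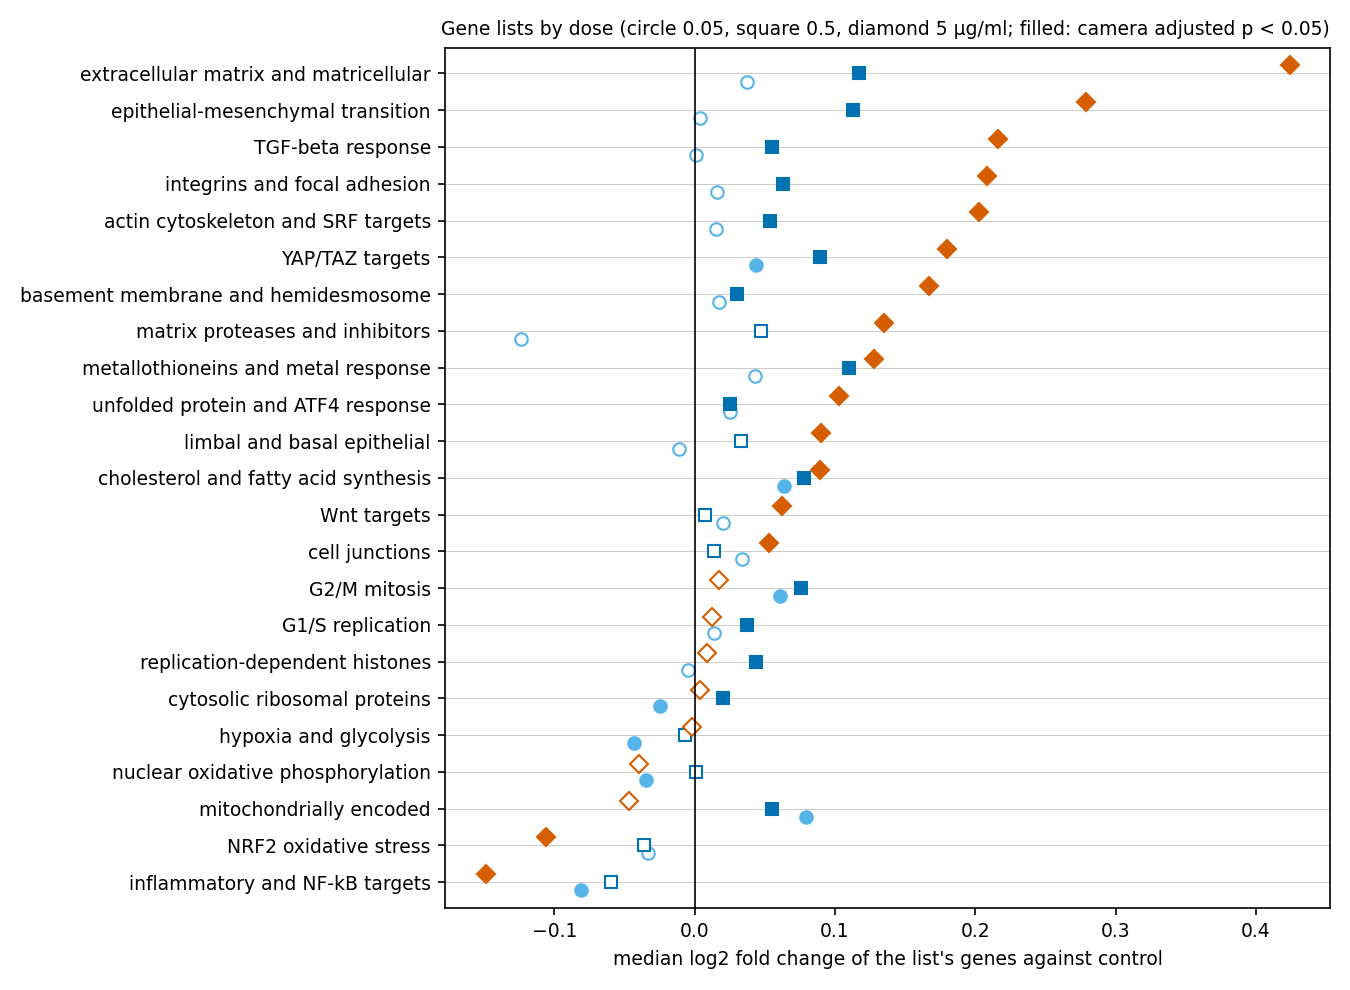
Median log2 fold change against control (horizontal axis) of gene lists called at 1 or more doses, at SPARC 0.05 (circle), SPARC 0.5 (square) and SPARC 5 (diamond). Filled symbols have a camera adjusted p under 0.05. The extracellular matrix list reaches 0.424 at SPARC 5, and the cholesterol and fatty acid synthesis list lies at 0.064, 0.078 and 0.089.

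SPARC 0.5 was compared with control to see which of these changes were present at a lower dose. FN1 went from 688 ± 48.3 to 1180 ± 71.3 CPM (log2 0.77 ± 0.06, adjusted p = 6.38e-07), THBS1 to 4410 ± 180 CPM (0.37 ± 0.06, adjusted p = 0.00139), PMEPA1 to 50.2 ± 2.73 CPM (0.42 ± 0.05, adjusted p = 5.25e-10) and TGFBI to 542 ± 9.86 CPM (0.22 ± 0.02, adjusted p = 3.65e-12), with n = 5 in each group. The sodium-calcium exchanger SLC8A1 rose by 0.54 ± 0.08, the peptide hormone gene APLN by 0.45 ± 0.10, the matrix gene CCDC80 by 0.41 ± 0.06 and FSTL1, of the SPARC family, by 0.35 ± 0.05. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), an early enzyme of sterol synthesis, went from 188 ± 6.06 to 237 ± 9.87 CPM (0.33 ± 0.03, adjusted p = 4.54e-15). VEGFA went from 158 ± 12.5 to 128 ± 6.20 CPM (−0.31 ± 0.05).

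The test called 517 genes at SPARC 0.5, of which 312 rose and 205 fell, and with library sizes only 577, of which 165 rose and 412 fell (60.3% and 28.6% higher). The number was 267 without SPARC 0.5 replicate 4 and 333 without control replicate 3. The 10 largest falls were all of genes under 5 CPM, and each lost its call when some single library was left out, such as GPER1, a membrane estrogen receptor (−0.69 ± 0.17, adjusted p = 0.00875, and 0.0513 without SPARC 0.5 replicate 2). Among genes that rose, MIR3648-2, LAMA1, COL10A1, CUX2 and WDPCP also lost their calls in this way. For COL10A1 the adjusted p was 0.2 without control replicate 2. Genes that rose at this dose were longer and poorer in GC than genes that fell: their median transcript length was 5752 against 3587 bases and their median GC content 42.2% against 57.8%. After a correction of each library for GC content and length, chosen after seeing the data, 254 of the 517 were called in the same direction. All 517 kept their sign, and the median size of their log2 fold change went from 0.167 (median SE 0.039) to 0.145 (0.038). The calls that ended thus do not show that GC content or length was the whole cause. These 517 were picked by the same changes, so the sign and size that remained do not show another cause either.

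At SPARC 0.5, 15 lists were called, all higher. Of 29 cholesterol and fatty acid synthesis genes, 12 rose and 0 fell (20 adjusted over the list alone; camera adjusted p = 5.91e-11), of 23 YAP/TAZ targets 6 and 0 (13 adjusted over the list alone; 4.07e-08), and of 24 extracellular matrix genes 6 and 2 (11 adjusted over the list alone; 4.23e-06). Of 25 TGF-beta response genes, 5 rose and 0 fell (9 adjusted over the list alone; 1.74e-05), of 18 genes of epithelial-mesenchymal transition 3 and 0 (3 adjusted over the list alone; 2.01e-05), and of 21 integrin genes 3 and 0 (8 adjusted over the list alone; 0.000224). MSMO1 (0.21 ± 0.03), SCD (0.15 ± 0.02), CCN1 (0.25 ± 0.05) and ITGB6 (0.29 ± 0.04) were members. These 6 lists kept their calls with an estimated correlation, and the other 9 did not. Of 30 G2/M genes, 7 rose (9 adjusted over the list alone; camera adjusted p = 3.22e-07, adjusted p = 0.222 with an estimated correlation), such as KIF11 (0.14 ± 0.03, and 0.10 with adjusted p = 0.0813 after the correction), a mitotic kinesin, and of 21 actin cytoskeleton genes 6 rose (9 adjusted over the list alone; 2.58e-06, adjusted p = 0.122 with an estimated correlation). Of 24 genes of the unfolded protein response, 5 rose (8 adjusted over the list alone; camera adjusted p = 0.00625, adjusted p = 0.202 with an estimated correlation). Histones had 0 calls of 18 (2 adjusted over the list alone; camera adjusted p = 0.00303, adjusted p = 0.557 with an estimated correlation), and metallothioneins 0 of 11 (0 adjusted over the list alone; 0.00382, adjusted p = 0.117 with an estimated correlation).

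The last 4 lists called at SPARC 0.5 did not pass with library sizes only. G1/S replication had 1 rise of 27 (4 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.177 with an estimated correlation, and 0.212 with library sizes only). Basement membrane had 3 rises of 22 (6 adjusted over the list alone; camera adjusted p = 0.0485, adjusted p = 0.483 with an estimated correlation, and 0.228 with library sizes only). Mitochondrially encoded genes had 0 calls of 13 (0 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.637 with an estimated correlation, and 0.0695 with library sizes only). Cytosolic ribosomal proteins had 0 of 28 (0 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.637 with an estimated correlation, and 0.504 with library sizes only), and their median log2 fold change turned from 0.02 to −0.003 with that scaling.

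SPARC 0.05 was compared with control for the lowest dose. HMGCS1 went from 188 ± 6.06 to 225 ± 5.91 CPM (log2 0.26 ± 0.03, adjusted p = 6.17e-10, n = 5 each), SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834), the desaturase that makes monounsaturated fatty acids, from 3090 ± 104 to 3430 ± 27.6 CPM (0.15 ± 0.02, adjusted p = 4.46e-08), and INSIG1, a sterol-regulated protein of the endoplasmic reticulum, from 142 ± 4.26 to 158 ± 5.85 CPM (0.16 ± 0.03, adjusted p = 0.0027). FN1 went to 885 ± 69.0 CPM (0.36 ± 0.06, adjusted p = 0.0114) and FSTL1 rose by 0.24 ± 0.05. IER3, an immediate early gene, went from 103 ± 5.25 to 85.7 ± 4.08 CPM (−0.26 ± 0.04, adjusted p = 2.8e-05), and ABCG1, which exports cholesterol, from 20.6 ± 1.72 to 16.4 ± 1.05 CPM (−0.32 ± 0.07, adjusted p = 0.0114). The call of ABCG1 was lost without control replicate 1 (adjusted p = 0.0696), SPARC 0.05 replicate 2 (0.0585) or replicate 3 (0.0631).

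The test called 61 genes at SPARC 0.05, of which 43 rose and 18 fell (33 and 36 of 69 with library sizes only, a share of rises of 70.5% against 47.8%). Without single libraries the number was 22 (SPARC 0.05 replicate 2), 34 (replicate 3), 33 (replicate 5), 34 (control replicate 2), 39 (control replicate 3) and 23 (control replicate 4). The genes that rose had a median transcript length of 9288 bases and GC content of 41.1%, against 3351 bases and 60.6% for those that fell and 3228 bases and 48.1% for genes not called. After the correction for GC content and length 11 genes were called, 7 of them among the 61 with the same direction. All 61 kept their sign, and the median size of their log2 fold change went from 0.151 (median SE 0.033) to 0.112 (0.032). HMGCS1 (0.23), SCD (0.14), INSIG1 (0.15) and IER3 (−0.22) were among the 11. FN1 (0.32, adjusted p = 0.0868) and FSTL1 (0.22, adjusted p = 0.0649) were not.

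At SPARC 0.05, 8 of 35 lists were called with camera. With an estimated correlation camera called 0, and 2 had an unadjusted p under 0.05. Of 29 cholesterol and fatty acid synthesis genes, 5 rose and 0 fell (19 adjusted over the list alone; camera adjusted p = 2.4e-11, adjusted p = 0.0738 with an estimated correlation). Their mean log2 CPM was 0.070 above control (exact permutation p = 0.00794, the smallest that 252 arrangements give, and 0.017 adjusted over 30 such tests on 5 lists picked after their values were seen), with all 5 samples above all 5 controls. Of 30 G2/M genes, 2 rose (6 adjusted over the list alone; camera adjusted p = 1.37e-06, adjusted p = 0.502 with an estimated correlation), and of 23 YAP/TAZ targets 1 rose (4 adjusted over the list alone; 0.0146, adjusted p = 0.502 with an estimated correlation). Mitochondrially encoded genes were higher with 0 calls of 13 (0 adjusted over the list alone; 0.00134, adjusted p = 0.545 with an estimated correlation). Lower lists were hypoxia and glycolysis with 0 calls of 21 (2 adjusted over the list alone; 0.00278, adjusted p = 0.308 with an estimated correlation) and inflammatory and NF-kB targets with 0 of 31 (0 adjusted over the list alone; 0.00706, adjusted p = 0.509 with an estimated correlation). Nuclear oxidative phosphorylation was lower with 0 of 26 (1 adjusted over the list alone; 0.0146, adjusted p = 0.509 with an estimated correlation), and so were cytosolic ribosomal proteins with 0 of 28 (0 adjusted over the list alone; 0.0229, adjusted p = 0.674 with an estimated correlation, and 0.176 after the correction).

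**Figure D3:**
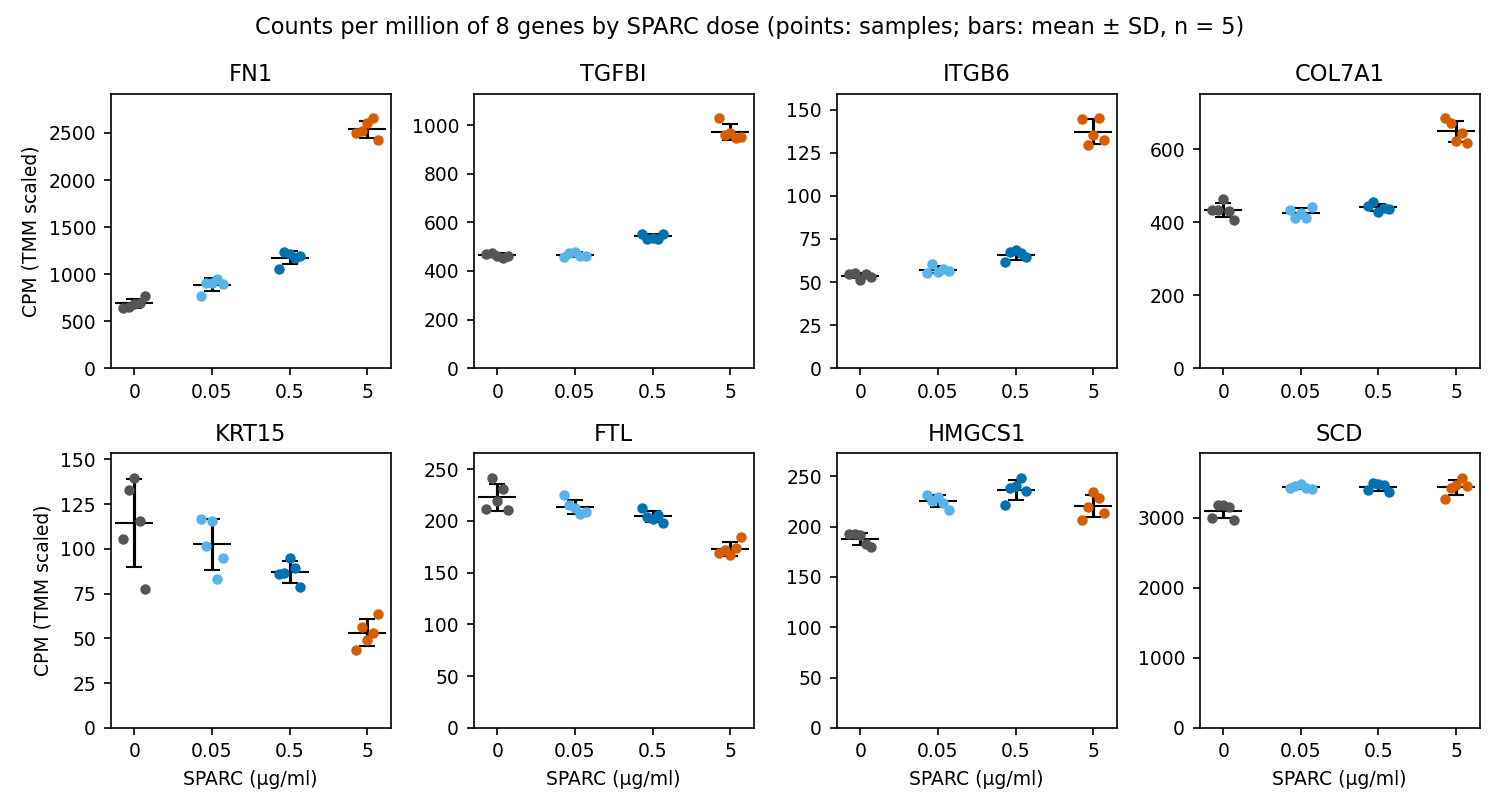
CPM (vertical axes, from 0) of 8 genes in every sample at 0, 0.05, 0.5 and 5 µg/ml SPARC, with mean ± SD (n = 5). FN1 steps from 688 to 885, 1180 and 2540 CPM, while SCD goes from 3090 to 3430, 3440 and 3430 CPM.

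The comparisons between doses ask whether the response grew with dose. From SPARC 0.5 to SPARC 5, FN1 rose by 1.11 ± 0.06 (adjusted p = 3.95e-10), ITGB6 by 1.06 ± 0.04, THBS1 by 1.03 ± 0.06, TGFBI by 0.84 ± 0.02 and COL7A1 by 0.56 ± 0.03, and KRT15 changed by −0.72. From SPARC 0.05 to SPARC 0.5, FN1 rose by 0.41 ± 0.06. In the cholesterol and fatty acid list, 4 genes of 29 rose and 3 fell between SPARC 0.05 and SPARC 5 (11 adjusted over the list alone; camera adjusted p = 0.409). The mean log2 CPM of this list, taken over genes that moved both ways, was 0.019 higher at SPARC 5 than at SPARC 0.05 (95% permutation interval −0.007 to 0.046, exact permutation p = 0.111, 0.167 adjusted over 30 such tests). The mean of the extracellular matrix list was 0.483 above control at SPARC 5, 0.128 at SPARC 0.5 and 0.022 at SPARC 0.05 (exact permutation p = 0.635 for the last, 0.657 adjusted).

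Counts of genes that differed were 1900 between SPARC 5 and SPARC 0.05 (1271 higher, 629 lower), 1100 between SPARC 5 and SPARC 0.5 (759 and 341) and 41 between SPARC 0.5 and SPARC 0.05 (36 and 5). With library sizes only the shares of genes higher went from 66.9% to 36.3%, from 69% to 46% and from 87.8% to 60%. The last count was 15 without SPARC 0.5 replicate 4, 19 without replicate 5, and 19, 16, 25 and 20 without SPARC 0.05 replicates 1, 2, 3 and 5. Between SPARC 5 and SPARC 0.05, 17 of 21 actin cytoskeleton genes rose (17 adjusted over the list alone; camera adjusted p = 1.67e-18) and 13 of 24 matrix genes (17 adjusted over the list alone; 4.51e-16), while 8 of 19 NRF2 genes fell (9 adjusted over the list alone; 4.42e-06). Between SPARC 5 and SPARC 0.5, 12 of 22 basement membrane genes rose (17 adjusted over the list alone; camera adjusted p = 4.53e-14). Between SPARC 0.5 and SPARC 0.05, 2 TGF-beta response genes of 25 rose (4 adjusted over the list alone; camera adjusted p = 2.12e-06). These 5 lists kept their calls with an estimated correlation.

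A test of any difference among the groups called 2529 genes, and a trend per dose step called 2541, of which 1561 rose and 980 fell (61.4% higher, and 30.6% with library sizes only). The steepest trends per dose step were those of IGFBP3 (1.96), XYLT1 (1.09) and ADAM19 (0.82) upward and of FLG (−0.50) downward. Genes called at each of the 3 doses against control numbered 25 higher, among them FN1, FSTL1, HMGCS1, MSMO1, SCD and INSIG1, and 7 lower. The 3 comparisons share their controls, and these numbers were not set against a value without a response. After the correction for GC content and length, 3 of the 25 (HMGCS1, SCD and INSIG1) and 0 of the 7 were still called at each dose. FN1, FSTL1 and MSMO1 (adjusted p = 0.0868, 0.0649 and 0.0613) were among those not called at SPARC 0.05. All 32 kept their sign there, with a median size of 0.143 before and 0.108 after. Of genes called at both SPARC 5 and SPARC 0.5, 255 were higher at both, 148 lower at both and 0 opposite. Independent calls would give 22 and 9.4. When each dose was set against a different part of the controls, the numbers were 89 and 39.6 in the mean of 10 splits, against 7.85 and 2.57. For SPARC 5 and SPARC 0.05 the genes higher and lower at both went from 30 and 10 to 8.5 and 1.9, against 1.09 and 0.36. For SPARC 0.5 and SPARC 0.05 they went from 32 and 9 to 6.6 and 0.9, against 0.18 and 0.05. Splitting the controls does not remove a GC content or length trend that the control libraries have in common. The values for independent calls also ignore that genes with many counts are easier to call at every dose. The excess therefore does not by itself show a shared response to SPARC. Simulated data with no shared response other than the shared controls had a correlation of log2 fold changes across genes of 0.501, against 0.64 here. The same values were 0.504 against 0.566 for SPARC 0.5 with SPARC 0.05. For SPARC 5 with SPARC 0.05 they were 0.5 against 0.429, a lower correlation than simulated. The covariance of this pair was higher than simulated (0.0122 against 0.00776), and 67.2% against 66.7% of genes had the same sign. The lower correlation alone thus does not show that less was shared. The simulated data held no GC content trend between libraries, so they do not separate such a trend from a response.

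**Figure D4:**
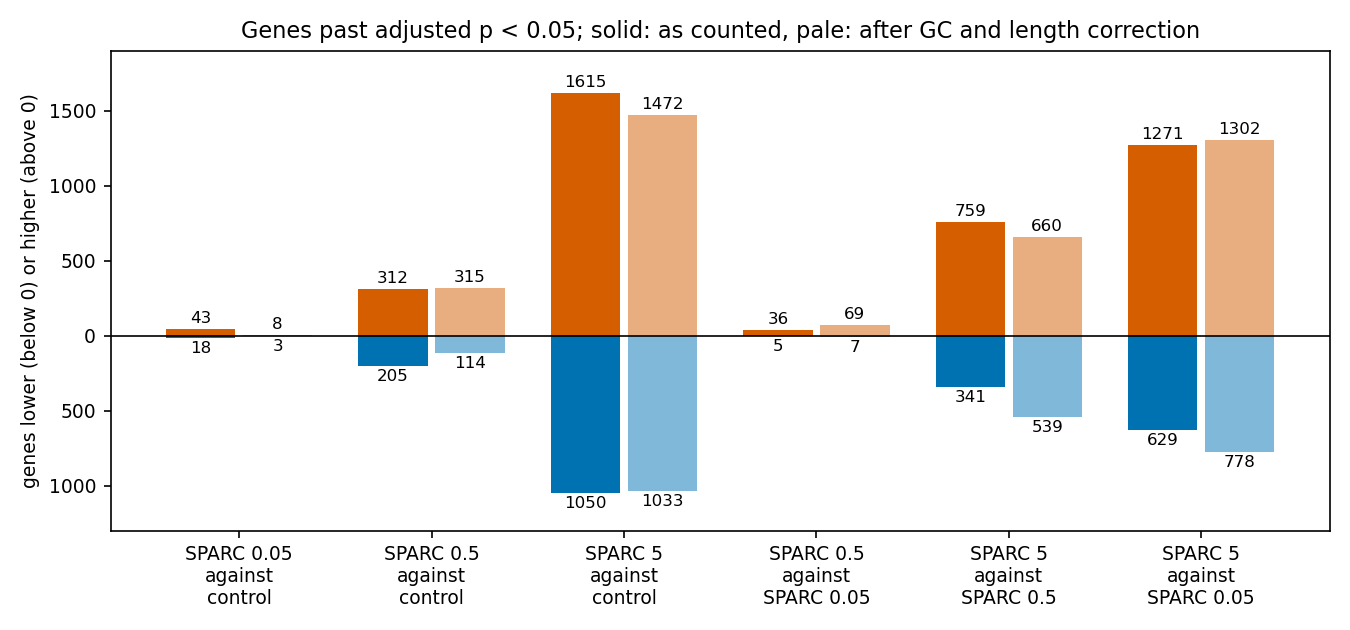
Number of genes with adjusted p under 0.05 in each comparison (vertical axis; above 0 higher, below 0 lower), as counted (solid) and after the correction for GC content and length (pale). SPARC 5 against control has 1615 higher and 1050 lower genes as counted, and 1472 and 1033 after the correction. Of the 2665 genes as counted, 1969 were called in the same direction after it.

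The comparison tables that the authors deposited call 2614 genes at SPARC 5 (1461 higher, 1153 lower), 549 at SPARC 0.5 (301 and 248) and 110 at SPARC 0.05 (64 and 46) at the same threshold. Of these, 2418, 457 and 59 were also called here, all with the same direction, and the log2 fold changes correlated across genes with r = 0.987, 0.984 and 0.98.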

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

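The tests of the SPARC treatment against held-out controls, of the shared controls, of a dose step, of a few abundant genes and of endotoxin were chosen only after the result they test was seen, and so was the correction for GC content and transcript length.

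Genes called at SPARC 0.05 were long when higher and rich in GC when lower. Relative to the mean of the 20 libraries, log2 CPM had a higher correlation with GC content in the control libraries (0.128 ± 0.106) than in the SPARC 0.05 libraries (−0.036 ± 0.032). The tables argue against library size: a share of 0.902 of the 61 genes was called in the same direction after every library was thinned to the smallest. A GC and length trend between libraries may account for part of these changes: after the trend was removed a share of 0.115 was called in the same direction. The median size of their log2 fold change went from 0.151 to 0.112 with an SE of 0.033 before and 0.032 after, so calls ended as estimates became smaller at a similar SE. All 61 kept their sign and most of the size remained, so the lost calls do not make the trend the whole cause. The 61 were picked by these same changes, so the size that remained does not show another cause either. In 1 set of simulated counts the libraries' trends were laid on, and 200 genes were raised 1.5-fold at SPARC 0.05. There 38 unchanged genes were called before the correction and 7 after, and 80% and 80.5% of the raised genes were called. Such a trend can thus give calls without a change. The raised genes changed by more than the 61, so power at their size was not measured. Whether the SPARC treatment contributed cannot be told apart from such a trend: when genes were called with 3 controls and measured against the other 2, a share of 0.831 of 350 calls over the 10 choices of controls had the same sign at SPARC 5 and 0.88 at SPARC 0.5, both between the bounds set for either answer. The choices overlap, so a gene can count more than once. Of the 350 calls, 114 came from control replicates 2, 3 and 4, which had the highest correlations with GC content among controls (0.164, 0.27 and 0.151). The labels do not give library batches, so no batch could be tested.

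The mean of the cholesterol and fatty acid synthesis genes was higher by about the same amount at each dose. The tables argue against the GC and length trend, since the list's mean log2 fold change at SPARC 0.05 after the correction was 1.058 times that before. Low chance values of the shared controls stay open. The largest exact permutation p over the 3 doses was 0.00794, but the list was picked after its means were seen and the 3 tests use the same 5 controls. The list's call at SPARC 0.05 was also lost with an estimated correlation (adjusted p = 0.0738). Between SPARC 0.05 and SPARC 5, the list's mean showed no step as large as that of the extracellular matrix list. The list was picked after its means were seen, so a smaller dose response of its mean stays open. The upper end of the 95% permutation interval for SPARC 5 over SPARC 0.05 was 0.046, under the mean's own change of 0.070 at SPARC 0.05. The interval of the extracellular matrix list for the same step was 0.342 to 0.588. For single members a dose response stays open, since 4 rose and 3 fell between these doses. Also open are SPARC itself and any other difference between control and treated cultures, such as the carrier of the protein, which was not tested because the labels give no carrier control.

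Of 68 tested genes of the matrix, integrin and TGF-beta response lists, 40 rose at SPARC 5. The tables argue against a few abundant genes distorting the scaling, since a share of 0.85 of the 40 members that rose (34) still rose with library sizes only, and against the GC and length trend, since a share of 0.95 (38) was called higher after the correction. Endotoxin carried with the recombinant protein stays open: the mean log2 CPM of inflammatory and NF-kB targets differed by −0.133 from control (95% permutation interval −0.320 to 0.071, exact permutation p = 0.135), which does not exclude a small rise. Other factors carried with the protein, TGF-beta among them, could give the same pattern and were not tested. A response to SPARC is thus a hypothesis.

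Other splits of the same samples into groups of the same sizes were tested, 100 for each count with the real split included. No other split drawn gave as many calls at SPARC 5 (1 split as large, the real one with 2665, against 720 in the highest other split), SPARC 0.5 (1 split, 517 against 46) or SPARC 0.05 (1 split, 61 against 3). The same held for SPARC 5 against SPARC 0.05 (1 split, 1900 against 203), SPARC 5 against SPARC 0.5 (1 split, 1100 against 96), SPARC 0.5 against SPARC 0.05 (1 split, 41 against 6), any difference (1 split, 2529 against 335) and the trend (1 split, 2541 against 292). These values argue against a chance arrangement of these libraries. They cannot exclude a chance difference between cultures or library preparations, because the labels give neither separate cultures nor batches. For the number of gene lists a chance arrangement could not be excluded: 9 of 100 splits called as many lists as the 16 at SPARC 5 (highest other 19), 5 as many as the 15 at SPARC 0.5 (highest other 17) and 15 as many as the 8 at SPARC 0.05 (highest other 12).

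Of 431 groups of 5 values examined, 24 held a value far from the other 4 by Dixon's criterion, where chance gives about 1 in 20, or 21.6. Among matrix and adhesion genes, THBS1 was at 4730 CPM in SPARC 0.5 replicate 5 (others 4280 to 4390) and LAMA3 at 764 CPM (700 to 705) in the same library. COL12A1 was at 408 CPM (374 to 383) and TGFBI at 1030 CPM (948 to 967) in SPARC 5 replicate 1, PMEPA1 at 115 CPM (126 to 131) and CALD1 at 178 CPM (172 to 173) in SPARC 5 replicate 5, and COL10A1 at 3.36 CPM (2.36 to 2.64) in SPARC 0.5 replicate 1. In control replicate 5, LTBP2 was at 95.5 CPM (105 to 107), DSP at 1060 CPM (1130 to 1140) and FZD10-AS1 at 0.483 CPM (0.148 to 0.242). In control replicate 4, IGFBP3 was at 0.441 CPM (0.0604 to 0.139), XYLT1 at 0.911 CPM (0.543 to 0.64) and IFIH1 at 13.6 CPM (11.2 to 11.8). In control replicate 2, CALR was at 657 CPM (623 to 631) and WFIKKN1 at 4.17 CPM (2.62 to 3.04), and in control replicate 1, VEGFA was at 179 CPM (148 to 157) and ABCA1 at 6.13 CPM (9.82 to 11.1).

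In SPARC 5 replicate 1, H2AC5P was at 3.52 CPM (others 0.416 to 1.31), and without that library its log2 fold change went from 1.84 to 1.12 and its call was lost (adjusted p = 0.056). In the same library IFIH1 was at 10.7 CPM (9.07 to 9.29). NPAS2 was at 11.6 CPM in SPARC 5 replicate 2 (9.68 to 9.92) and IFIT2 at 2.59 CPM in SPARC 5 replicate 4 (1.4 to 1.72). In SPARC 0.5, HSPA5 was at 861 CPM in replicate 1 (910 to 923), GPER1 at 1.7 CPM in replicate 2 (2.59 to 2.88) and INSIG1 at 149 CPM in replicate 5 (162 to 163).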

How the results depend on the processing

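The correction for GC content and length, thinning, leaving out 2 SPARC 5 libraries, and library sizes only for lists and named genes were chosen after seeing the data; the other alternatives were fixed before. Numbers of genes at SPARC 5 (2665), for any difference (2529), for the trend (2541) and for SPARC 5 against either lower dose (1900 and 1100) stayed within 1.5 times their value under every alternative run. Leaving out 1 library gave 2236 to 2662 genes at SPARC 5, 2153 to 2576 for any difference, 2089 to 2535 for the trend, 1543 to 1937 for SPARC 5 against SPARC 0.05 and 850 to 1142 for SPARC 5 against SPARC 0.5. Without both SPARC 5 libraries that stood apart on the second component, 2207 genes were called at SPARC 5. The 61 genes at SPARC 0.05 became 174 with DESeq2 and 11 after the GC and length correction, and 22 to 82 without 1 library (22 without SPARC 0.05 replicate 2, 82 without control replicate 5). The 517 at SPARC 0.5 became 267 to 608 without 1 library (267 without SPARC 0.5 replicate 4), and 429 after the correction. The 41 between SPARC 0.5 and SPARC 0.05 became 81 with DESeq2, 69 with limma voom, 70 with no filter, 66 with replicate number as a block, 76 after the correction, and 15 to 52 without 1 library (15 without SPARC 0.5 replicate 4). The cause of each of these moves was not tested. Replicate numbers did not pair the samples: 30 correlations between samples of the same number, after group means were removed, lay between −0.025 and 0.0449. The 16 lists at SPARC 5 became 26 with fry, which does not compare a list with other genes, and 14 to 18 without 1 library. The 15 at SPARC 0.5 became 6 with an estimated correlation and 9 (without control replicate 1) to 17 without 1 library, and the 8 at SPARC 0.05 became 0 with an estimated correlation, 2 with fry and 6 to 12 without 1 library (12 without SPARC 0.05 replicate 4). Camera with an estimated correlation gave 2 of 35 lists an unadjusted p under 0.05 there, where its default called 8.

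No named gene reversed its direction under the alternatives checked gene by gene, with DESeq2 only where it gave an adjusted p. Named genes were not checked with no filter, the stricter filter, protein-coding genes alone or only the groups compared. Of 95 genes the naming rule took at SPARC 5, 12 lost their call without some single library, 2 after the GC and length correction, 5 with library sizes only and 4 with limma voom. Of 58 at SPARC 0.5 these numbers were 28, 18, 7 and 8, and of 26 at SPARC 0.05 they were 18, 20, 1 and 5. DESeq2 ended no call of a named gene to which it gave an adjusted p. It gave one to 94 of the 95 genes at SPARC 5, 58 of the 58 at SPARC 0.5 and 19 of the 26 at SPARC 0.05. For SPARC 5 against SPARC 0.05 and against SPARC 0.5 it gave one to 5 of 10 in each. Depth set a limit for genes with few counts: 5% of the genes tested had a mean under 0.229 CPM.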

Other observations

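The observations here were chosen after their values were seen. Members of the SPARC family of secreted proteins did not move alike. SPOCK1, a testican proteoglycan, rose at SPARC 5 from 0.585 ± 0.263 to 1.98 ± 0.563 CPM (log2 1.74 ± 0.34, edgeR adjusted p = 7.59e-05), with 0.508 ± 0.235 CPM at SPARC 0.05. FSTL1 rose at each dose, by 0.24 ± 0.05, 0.35 ± 0.05 and 0.41 ± 0.05 in order of dose, and its call at SPARC 0.05 was lost after the GC and length correction (adjusted p = 0.0649). SMOC1 fell at SPARC 5 by 1.08 on the log2 scale, from 2.39 ± 0.313 to 1.12 ± 0.332 CPM. SPARCL1 (0.84 ± 0.51, adjusted p = 0.342) and SPOCK2 (0.14 ± 0.29, adjusted p = 0.843) did not pass at SPARC 5.

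Of 2 genes of sterol export looked at, with no list of such genes tested, ABCG1 was at 20.6 ± 1.72 CPM in control, 16.4 ± 1.05 at SPARC 0.05, 16.6 ± 1.57 at SPARC 0.5 and 21.3 ± 1.33 at SPARC 5 (n = 5 each). It was higher at SPARC 5 than at SPARC 0.05 (log2 0.37 ± 0.07, adjusted p = 2.74e-05) and than at SPARC 0.5 (0.36 ± 0.07, adjusted p = 8.88e-05). Its call at SPARC 0.05 was lost without control replicate 1 (adjusted p = 0.0696), SPARC 0.05 replicate 2 (0.0585) or replicate 3 (0.0631). ABCA1, which exports cholesterol to apolipoproteins, rose at SPARC 5 from 9.43 ± 1.91 to 16.8 ± 2.39 CPM (0.83 ± 0.10, adjusted p = 1.54e-08), the direction of the sterol synthesis list. It did not pass at SPARC 0.05 (−0.022, adjusted p = 0.977) or SPARC 0.5 (0.19, adjusted p = 0.444). IER3 had the same order as ABCG1: 103 ± 5.25 CPM in control, 85.7 ± 4.08 at SPARC 0.05, 92.9 ± 5.32 at SPARC 0.5 and 104 ± 6.22 at SPARC 5, with a difference of 0.28 ± 0.04 between SPARC 5 and SPARC 0.05 (adjusted p = 6.11e-08).

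Within the cholesterol and fatty acid list, FASN, the fatty acid synthase, had log2 values of 0.11 at SPARC 0.05 (adjusted p = 0.268) and −0.0017 at SPARC 5 (adjusted p = 0.986), and its difference between these doses was −0.11 ± 0.03 (adjusted p = 0.0579). After the GC and length correction FASN rose at SPARC 0.05 (0.14 ± 0.02, adjusted p = 1.68e-07), as did MVD (0.14) and DHCR7 (0.10).

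TERT, the telomerase gene with which this line was immortalized, fell from 59.3 ± 2.98 CPM in control to 47.4 ± 2.97 CPM at SPARC 0.5 (−0.33 ± 0.05, adjusted p = 4.38e-07) and 42.2 ± 1.17 CPM at SPARC 5 (−0.49 ± 0.05, adjusted p = 2.83e-15). It was also called lower at SPARC 0.05 (−0.183). That call was lost without some single libraries, such as SPARC 0.05 replicate 2 (adjusted p = 0.238), and after the GC and length correction. The counts do not tell reads of the introduced copy from reads of the cell's own gene.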
